A study of Sus scrofa with 6 samples.

How the data were processed

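Total RNA of primary porcine endometrial epithelial cells was sequenced after seminal exosome treatment or none, with 3 libraries in each of 2 groups. Libraries were made with a stranded mRNA kit, per the labels' protocols. Reads were demultiplexed with bcl2fastq 1.8.4, aligned with TopHat and quantified with Cufflinks on the Sscrofa11.1 assembly, per the submitters' processing notes. The versions of TopHat and Cufflinks, the annotation release and any filter are not given in the sources used here. The deposited values were taken as FPKM made by the authors, which are fragments scaled by transcript length and library size. No header states the unit, which was taken from the tool named in the submitters' processing notes and from the values. The deposited table held 10916 genes or gene pairs, of which 1 had no values, and the lowest value among the other 10915 was 0.0882. Genes with a 0 in any library were absent from the table, so a gene silent in 1 group cannot be seen here. The depth of the libraries is unknown, since no counts were given and the low values showed no steps of whole reads, so no counting intervals or floors are given. Count models were not used for the same reason.

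Samples were grouped by their titles, and columns were matched to samples by name. Values were transformed as log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left out 69 genes. A fold change on this scale understates the change of genes with low FPKM. Each gene was tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, 4 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes are from limma throughout. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

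Before the data were examined, 30 gene lists were fixed for the tissue, the treatment and other cell types that a primary culture can hold, together with the tests, the alternatives and the rule for named genes. The 26 lists with at least 3 members among the genes tested were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, and fry tests whether the genes of a list move, on balance, in 1 direction. The lists held 696 different symbols, of which 388 were found, and 47 matched list entries were found through the reference gene table. Errors in this matching were found and corrected after the results had been seen. Adducin had entered the cholesterol list through a synonym, and other genes had entered lists under a symbol that belonged to another gene. The number of passing lists was 8 before and after that correction.

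The rule for named genes took up to 12 passing genes in each direction. Where fewer passed, it took up to 6 in each direction by the smallest p among genes whose groups did not overlap, and these are said not to pass. It also took the 3 members of each list with the smallest p, and the 3 marker genes of each cell type with the highest mean. Genes outside the rule are said to be chosen after their values were seen. The separate values of 2 members of the cholesterol list are not reported here, and both are counted in the list.

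Gene symbols were those of the deposited table. Of the genes, 2607 had no symbol and 1038 of these were named from the reference table. Another 17 symbols had been turned into dates, of which 16 were replaced. The identifiers of 7494 genes (68.7%) were found in the reference table. No genome was used here, so no coordinates are given. Pairs of libraries differed by an SD of log2 ratios from 0.23 to 0.27 within the control group and from 0.29 to 0.32 within the exosome group. No library was therefore a copy of another. Pairs of a control and an exosome library differed by 0.26 to 0.32, so the libraries did not separate by group on this measure. Exosome replicate 2 was nearer control replicates 2 and 3 (0.26 each) than exosome replicates 1 and 3 (0.31 and 0.32).

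The scripts were tested on simulated data with 10915 genes and independent noise for the comparison of exosome with control, in 10 runs. They called 49.2% of genes changed 1.25-fold, 94.2% at 1.5-fold, 99.4% at 2-fold and 100% at 4-fold, and 0.096% of unchanged genes. Changes were planted only in genes well above the filter, so the power for low genes was not measured. Over the runs 500 genes were planted at each fold, which eases the adjusted threshold, so these shares may overstate the power in the real data. A list of 20 genes lowered 1.2-fold was called in 10 of 10 runs, and 0 of 200 unchanged lists were called by camera. The simulated genes were independent, so these list counts do not cover lists whose genes vary together. Alternatives were other pseudocounts, filters, scalings and variance models, the replicate number as a block, each library left out and each replicate number left out, and, chosen after seeing the data, list members of another reference symbol left out.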

Results

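Gene expression was measured by RNA sequencing in primary cultures of porcine endometrial epithelial cells, the cells that line the uterus, at passage 3. In the exosome group the cells received 10 µg per well of exosomes, membrane vesicles that were precipitated from the sperm-rich part of boar seminal fluid, for 48 h. The control group received none, per the design text, and each group held 3 libraries. The deposited table gave values for 10915 genes in all 6 libraries, with FPKM sums of 728400 ± 6270 in the control and 703300 ± 11360 in the exosome libraries (SD, n = 3; exact permutation p = 0.1, two-sided). The sequencing depth is unknown, because the table holds no counts. No label says whether the libraries of a group came from separate uteri or wells, so the p-values measure the spread between these libraries, which may be technical.

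Exosome treatment was compared with no treatment to ask which transcripts differ in endometrial epithelial cells after contact with seminal exosomes. CYP1A1 (ENSSSCG00000001906), a cytochrome P450 induced through the aryl hydrocarbon receptor, was at 56.4 ± 23.0 FPKM in the control and 9.67 ± 3.66 in the exosome libraries (SD, n = 3 per group), a log2 change of -2.41 with an SE of 0.34. ANKH (ENSSSCG00000016784), a membrane protein of pyrophosphate export, was at 176.0 ± 28.7 and 91.8 ± 11.4 FPKM (log2 change -0.93). TNFSF15 (ENSSSCG00000020784), a cytokine of the tumour necrosis factor family, was at 6.23 ± 0.433 in the control and 11.8 ± 1.62 FPKM in the exosome libraries (log2 change 0.82). AQP9 (ENSSSCG00000004597), a water and glycerol channel, was at 2.43 ± 0.181 and 5.02 ± 0.805 FPKM (log2 change 0.80). In each of these genes the 3 exosome libraries lay beyond the 3 control libraries on the same side, but none passed the test over all genes, with an adjusted p of 0.118 for all 4.

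ENC1 (ENSSSCG00000014072), an actin-binding Kelch protein, was higher in the exosome libraries, at 176.3 ± 5.67 FPKM against 125.1 ± 6.91 (log2 change 0.49, adjusted p = 0.0833). CRYM (ENSSSCG00000007849), a thyroid hormone-binding protein of the cytosol, was lower, at 32.3 ± 0.782 against 44.9 ± 1.48 FPKM (log2 change -0.46, adjusted p = 0.0833). SFXN3 (ENSSSCG00000022005), a mitochondrial carrier of the sideroflexin family, was at 0.881 ± 0.0622 against 2.65 ± 0.380 FPKM (log2 change -0.95, adjusted p = 0.0833). The other genes named by the smallest p in each direction were higher for ANKRD1, ABCC2 and ADM (log2 changes 0.41, 0.43 and 0.34) and lower for GPR110 and FXYD3 (log2 changes -0.68 and -0.41). ADM encodes the vasodilator peptide adrenomedullin, ABCC2 an exporter of organic anions, and FXYD3 a regulator of the sodium pump. These 5 had adjusted p-values from 0.117 to 0.166.

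**Figure D1:**
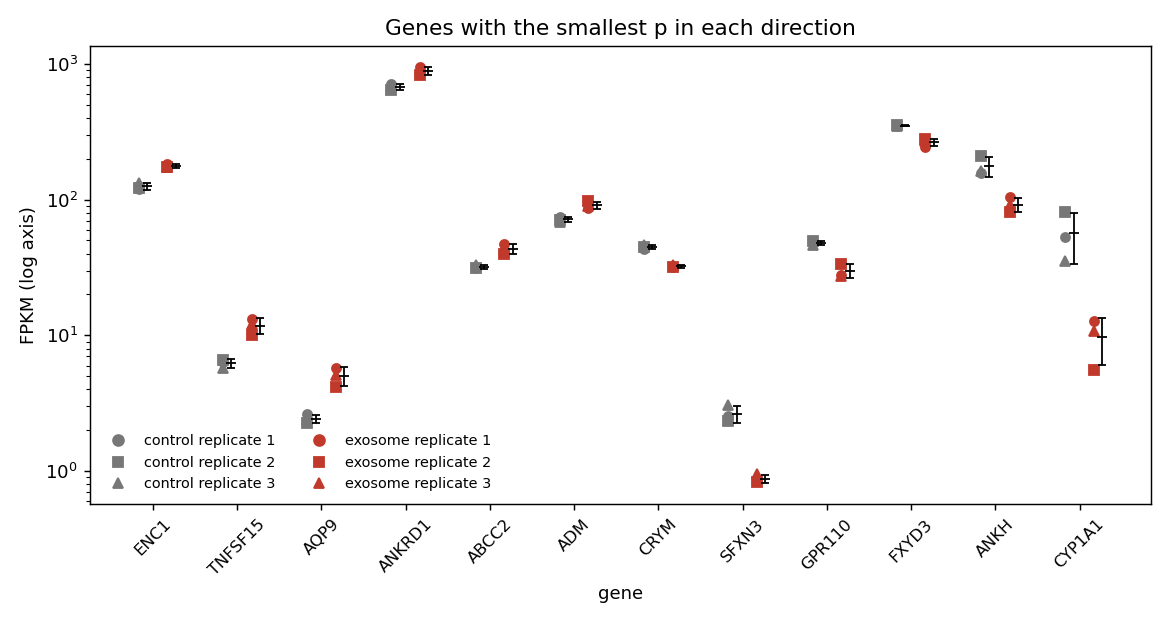
FPKM of the 12 genes with the smallest p in each direction, on a log axis. Each point is a library, grey for control and red for exosome, and the black bars give the mean and SD of each group (n = 3); in every gene shown the groups do not overlap, which was a condition for choosing it, and none of the 12 passed an adjusted p of 0.05.

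Across the 10846 genes tested, 0 passed an adjusted p of 0.05 in limma, and 3 (ENC1, CRYM and SFXN3) lay under 0.10. At an unadjusted p under 0.05 there were 1362 genes, 549 higher and 813 lower, where chance gives 542.3. The groups did not overlap in 18.7% of genes, where chance gives 10% for 3 against 3. The median log2 change of all genes tested was -0.00229. The count rested on single libraries: without exosome replicate 2, 297 genes passed (93 higher, 204 lower), among them the 12 genes named above, and without replicate 2 of both groups 58 passed. Without control replicate 3, and without replicate 3 of both groups, 1 gene passed each time (the unnamed ENSSSCG00000027411 and Metazoa_SRP, chosen after their values were seen).

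Genes of cholesterol synthesis and other targets of the SREBP transcription factors fell together in the exosome libraries, with a median log2 change of -0.50 over 22 members. All 22 had a negative log2 change, and 20 fell when p was adjusted over the list alone, against 0 over all genes tested in limma and 20 at an unadjusted p under 0.05. The members varied together, with an estimated correlation of 0.943, so these 20 are not independent results. Without exosome replicate 2, 20 of the 22 passed over all genes tested. MVK, mevalonate kinase, fell from 20.2 ± 1.30 to 13.2 ± 2.67 FPKM. PMVK, the next enzyme of the pathway, fell from 21.9 ± 2.32 to 15.6 ± 2.01 FPKM. TM7SF2, a sterol reductase, fell from 28.7 ± 3.06 to 15.2 ± 5.41 FPKM. Of 2 members chosen after their values were seen, INSIG1, the sterol-responsive anchor of SREBP, fell from 59.0 ± 11.05 to 30.9 ± 20.4 FPKM. HMGCS1, which makes HMG-CoA, fell from 112.5 ± 16.0 to 61.0 ± 35.0. The list passed camera at an adjusted p of 3.78e-15, and no longer passed, at adjusted p = 0.507 with an estimated correlation. The list median of each exosome library relative to the control mean was -0.78, -0.12 and -0.66 for replicates 1, 2 and 3, and the control libraries lay from -0.11 to 0.06. The exact permutation p was 0.1, two-sided, the smallest that 3 against 3 allows.

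**Figure D2:**
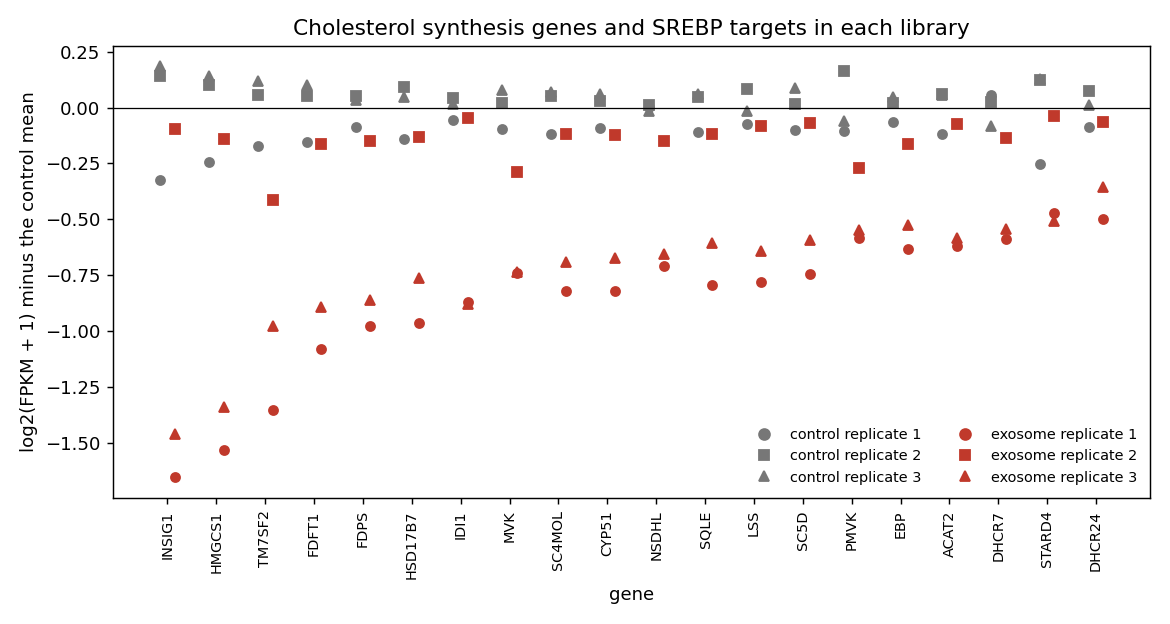
Log2(FPKM + 1) of 20 of the 22 cholesterol synthesis genes and SREBP targets in each library, minus the control mean of the gene. Each point is a library, grey for control and red for exosome; over all 22 members exosome replicates 1 and 3 lie at list medians of -0.78 and -0.66, and exosome replicate 2 at -0.12 lies near control replicate 1 at -0.11.

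Transcripts encoded by the mitochondrial genome, which make subunits of the respiratory chain, fell in the exosome libraries, with a median log2 change of -0.34 over 12 members. All 12 fell when p was adjusted over the list alone, against 0 over all genes tested in limma and 12 at an unadjusted p under 0.05. These members also varied together, with an estimated correlation of 0.615. Without exosome replicate 2, 11 of the 12 passed over all genes tested. ND5 fell from 3195 ± 78.9 to 2522 ± 198 FPKM, MT-ND4 from 1996 ± 70.3 to 1535 ± 174, and COX3 from 12850 ± 344 to 10170 ± 1102. Their share of all FPKM was 6.34% ± 0.0842 in the control and 5.20% ± 0.529 in the exosome libraries (SD, n = 3; exact permutation p = 0.1, two-sided). The list passed camera at an adjusted p of 5.01e-12, with adjusted p = 0.507 with an estimated correlation. Exosome replicate 2 again lay closest to the controls among the exosome libraries, with a list median of -0.16 against -0.43 and -0.45. Nuclear genes of oxidative phosphorylation had a median log2 change of -0.01 over 24 members and did not pass (adjusted p = 0.302). COX5B, UQCRC1 and COX4I1 were at log2 changes of -0.11, -0.09 and -0.08. The median of these nuclear genes was -0.04 without exosome replicate 1 (camera adjusted p = 0.0657) or control replicate 3, and 0 without exosome replicate 2.

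Cell cycle genes rose as a list in the exosome libraries, by a median log2 change of 0.14 over 25 members, 22 of them higher. BUB1B, a spindle checkpoint kinase, was at 24.1 ± 0.762 FPKM in the control and 29.2 ± 2.30 in the exosome libraries (log2 change 0.26), and BUB1 at 22.6 ± 0.938 and 25.7 ± 0.205. TOP2A, a DNA topoisomerase of dividing cells, was at 46.4 ± 1.76 and 54.0 ± 4.12. No member passed on its own, with 0 in limma both adjusted over the list alone and over all genes tested, and 11 at an unadjusted p under 0.05. The list passed camera at an adjusted p of 1.43e-06, with adjusted p = 0.507 with an estimated correlation. Without exosome replicate 1 the median was 0.08, still past the threshold at an adjusted p of 0.00031.

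Proinflammatory cytokines and chemokines rose as a list, with a median log2 change of 0.19 over 14 members, while the members moved in both directions. Adjusted over the list alone, 4 rose and 1 fell, against 0 over all genes tested in limma, with 5 higher and 2 lower at an unadjusted p under 0.05. CXCL8, a neutrophil attractant, rose from 270.2 ± 60.5 to 466.6 ± 113 FPKM (log2 change 0.78). CXCL2, of the same family, rose from 123.9 ± 20.5 to 189.8 ± 38.0 FPKM, and AMCF-II, a porcine neutrophil chemokine, from 15.6 ± 1.71 to 27.8 ± 9.73. The remaining passing members were IL1A, chosen after its values were seen, which rose (log2 change 0.39), and LIF, a cytokine of embryo implantation, which fell (log2 change -0.32). The list passed at an adjusted p of 0.0306, with adjusted p = 0.564 with an estimated correlation. The call was also lost without control replicate 2 (adjusted p = 0.0531), without control replicate 3 (0.106), without exosome replicate 1 (0.0781) and without replicate 3 of both groups (0.125). The identifier of TNFSF10, 1 of the 5 higher members, is listed under GHSR in the reference table. In an alternative chosen after seeing the data, which left out members of any list whose identifier has another symbol there, the median was 0.15 and the call was lost (adjusted p = 0.0604).

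Hypoxia and glycolysis genes rose as a list by a median log2 change of 0.05 over 24 members, 15 higher and 9 lower. Adjusted over the list alone, 4 rose (ADM, HK2 and, chosen after their values were seen, SLC2A3 and PDK1) and PFKFB4 fell, against 0 over all genes tested in limma, with 6 higher and 2 lower at an unadjusted p under 0.05. ADM was at 71.4 ± 2.99 FPKM in the control and 90.8 ± 5.19 in the exosome libraries. HK2, a hexokinase, was at 24.6 ± 0.777 and 30.6 ± 2.70 FPKM, and PFKFB4, a regulator of glycolysis, at 8.13 ± 0.400 and 6.39 ± 0.468. The list passed at an adjusted p of 0.0306, with adjusted p = 0.564 with an estimated correlation. The call ended without exosome replicate 2 (median 0.03, adjusted p = 0.520), exosome replicate 3 (0.0503) or control replicate 3 (0.145). It also ended without replicates 2 or 3 of both groups (0.483 and 0.171), without the intensity trend (0.0682) and with the replicate number as a block.

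Markers of endometrial epithelium fell as a list in the exosome libraries, with a median log2 change of -0.12 over 14 members, 13 of them lower. Adjusted over the list alone, 5 fell (ELF3, CLDN4, CLDN3, CD24 and MUC1), against 0 over all genes tested in limma and 7 at an unadjusted p under 0.05. ELF3, an epithelial transcription factor, fell from 195.0 ± 6.18 to 165.5 ± 9.22 FPKM and CLDN4, a tight junction claudin, from 1029 ± 33.9 to 811.9 ± 117. CLDN3 fell from 496.8 ± 51.6 to 370.0 ± 58.6 FPKM; its identifier is listed under CLDN9 in the reference table, so the value is uncertain between these related genes. The abundant markers CD24, KRT19 and KRT8 had log2 changes of -0.25, -0.13 and -0.12, and EPCAM, listed as TACSTD1 and chosen after its values were seen, was at 345.8 ± 12.5 and 357.9 ± 15.3 FPKM. The list passed at an adjusted p of 3.87e-05, with adjusted p = 0.507 with an estimated correlation, and its median was -0.08 with quantile normalization. Markers of stromal cells and fibroblasts did not pass, with a median log2 change of -0.12 over 7 members (adjusted p = 0.203). Among them CD90 fell from 2328 ± 93.7 to 1849 ± 69.4 FPKM, the 1 member past the threshold adjusted over the list alone. Without exosome replicate 2, ELF3, CLDN4, CD24 and CD90 passed over all genes tested.

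Epithelial junction genes, 4 of which are also among the 14 epithelial markers, fell as a list with a median log2 change of -0.05 over 19 members, 16 of them lower. CRB3, a polarity protein of tight junctions, fell from 88.8 ± 3.57 to 75.9 ± 3.57 FPKM, and with CLDN4 and CLDN3 it made up the 3 members past the threshold adjusted over the list alone, against 0 over all genes tested in limma, with 7 lower and 1 higher at an unadjusted p under 0.05. TJP1, a tight junction scaffold chosen after its values were seen, was at 59.5 ± 3.16 and 59.1 ± 7.46 FPKM. The list passed at an adjusted p of 0.0123, with adjusted p = 0.507 with an estimated correlation. The call was lost without exosome replicate 3 (adjusted p = 0.127) and without replicate 3 of both groups (0.171). The median moved between -0.02 without control replicate 2 and -0.11 without exosome replicate 2. It was -0.09 without control replicate 1, -0.08 without exosome replicate 1, -0.08 without replicate 1 of both groups and -0.09 without replicate 2 of both groups.

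Immediate early genes, which respond within minutes to growth factors and stress, fell as a list by a median log2 change of -0.09 over 13 members, 11 of them lower. FOS fell from 27.4 ± 1.28 to 22.3 ± 1.41 FPKM and was the 1 member past the threshold adjusted over the list alone, against 0 over all genes tested in limma and 2 at an unadjusted p under 0.05. DUSP5 and DUSP1 had log2 changes of -0.23 and -0.13. The list passed at an adjusted p of 0.0306, with adjusted p = 0.507 with an estimated correlation. The call was lost without exosome replicate 1 (median -0.04, adjusted p = 0.107), exosome replicate 3 (0.143), control replicate 1 (0.0653), and replicate 1 or 3 of both groups (0.172 with a median of -0.05, and 0.171). It was also lost with quantile normalization (0.0892) and without the intensity trend (0.0529). The median was -0.14 without exosome replicate 2.

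**Figure D3:**
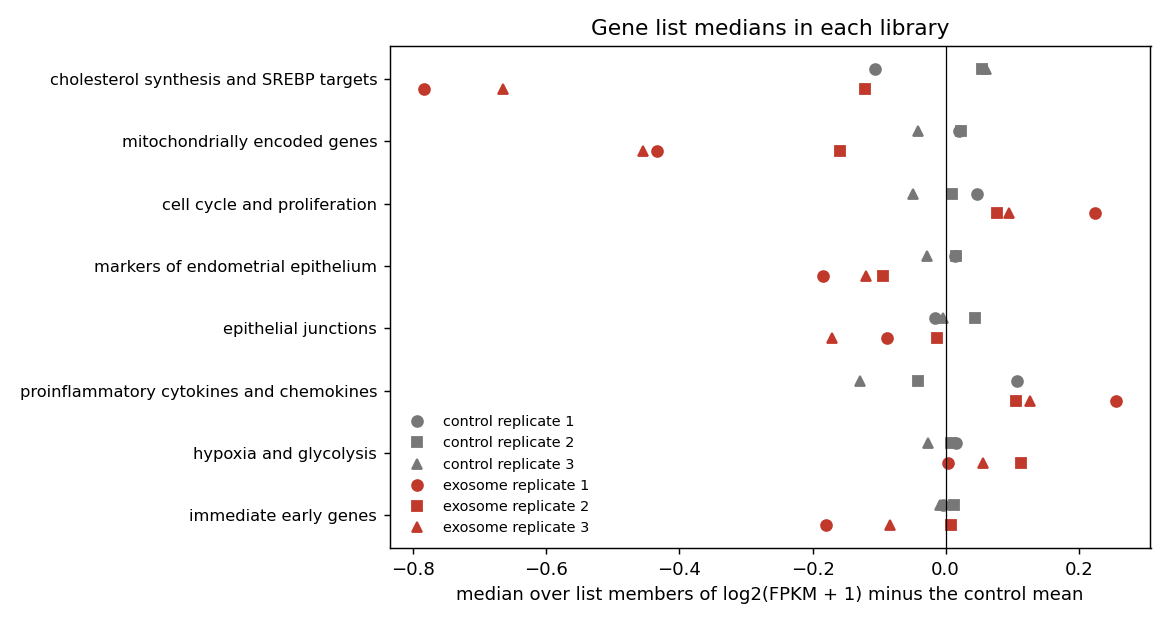
Median over the members of each of the 8 passing gene lists of log2(FPKM + 1) minus the control mean of the gene, in each library. Each point is a library, grey for control and red for exosome, with the shape giving the replicate. The exosome libraries lie apart from the controls for the cholesterol, mitochondrial, cell cycle and endometrial epithelium lists and overlap them for the other 4 lists. They also lie apart for the complement and prostaglandin lists, which did not pass and are not drawn, so separation is not particular to passing lists.

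Prostaglandin genes did not pass as a list (median log2 change -0.04 over 10 members, adjusted p = 0.336). Their median was -0.02 without exosome replicate 1 and -0.07 without control replicate 3. When p was adjusted over the list alone, 2 members fell. PTGS2, the inducible cyclooxygenase, fell from 356.1 ± 30.8 to 238.5 ± 47.7 FPKM (log2 change -0.59), and PLA2G4A, the phospholipase that releases arachidonic acid, from 99.9 ± 6.14 to 81.4 ± 5.82. PTGER2, a receptor for prostaglandin E, was at 2.20 ± 0.114 and 2.77 ± 0.272 FPKM and did not pass. Genes of endometrial receptivity and embryo signalling did not pass either (adjusted p = 0.951 over 21 members), and their median log2 change of 0.01 differed in sign from their mean of -0.0059 and from the test. RBP4, a retinol carrier, fell from 2865 ± 96.1 to 2327 ± 138 FPKM adjusted over the list alone, the 1 member to do so, and LIF and MUC1 had log2 changes of -0.32 and -0.21. TGF-beta genes had a median log2 change of -0.07 (adjusted p = 0.493), which was -0.01 without control replicate 3 and -0.02 without exosome replicate 1. ID1, an inhibitor of differentiation, rose from 100.0 ± 5.49 to 124.5 ± 5.85 FPKM as the 1 member past the threshold adjusted over the list alone, and TGFB1 and SMAD2 had log2 changes of -0.23 and -0.16. The list passed without exosome replicate 2 (median -0.12, adjusted p = 0.0381) or replicate 2 of both groups (-0.13, 0.0316). Extracellular matrix genes had a median of -0.02 (adjusted p = 0.736). TIMP-2, an inhibitor of matrix proteases, fell from 174.5 ± 2.04 to 142.8 ± 6.55 FPKM as the 1 such member, and THBS1 and MMP7 had log2 changes of 0.30 and -0.09. That list passed without exosome replicate 2 (median -0.11, adjusted p = 0.0195), and its median was 0.09 without exosome replicate 3. PTGS2, PLA2G4A, RBP4, ID1 and TIMP-2 passed over all genes tested without exosome replicate 2.

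No member passed, adjusted over the list alone, in the other lists that missed the threshold. Among innate immune lists, complement had a median log2 change of -0.13 (adjusted p = 0.121; CLU, CFD listed as DF, and CFI at -0.32, -0.37 and 0.16). It passed without exosome replicate 1 (0.0305), exosome replicate 3 (0.0384) or replicate 1 of both groups (0.0392). The median was 0.08 for NF-kB signalling (0.218; NFKBIZ, NFKBIA and NFKBIB at 0.24, 0.11 and 0.13), and -0.11 for antimicrobial and acute phase proteins (0.262; SLPI, MUC1 and WFDC2 at -0.33, -0.21 and -0.26). Interferon-stimulated genes had a median of -0.04 over 29 members (0.443; IRF9, ISG12(A) and DDX60 at -0.36, -0.31 and -0.17). The median was -0.06 for Toll-like and NOD-like receptors (0.418; MYD88, TLR4 and TIRAP at -0.09, -0.16 and -0.24), and 0.03 for antigen processing (0.548; SLA-6 and PSMB9 at -0.12 and 0.19, and B2M, which has 2 identifiers, at 0.12 and 0.05). Among stress lists, the unfolded protein response had a median of 0.06 (0.121; VLDLR, SLC3A2 and CHAC1 at 0.19, 0.20 and 0.18). It passed without exosome replicate 1 (0.00447), control replicate 1 (0.0311) or replicate 1 of both groups (0.000806), and with quantile normalization (0.0240). For oxidative stress and NRF2 targets it was 0.07 (0.190; PRDX1, TXNRD1 and GCLM at 0.21, 0.56 and 0.18). The medians of exosome replicates 1, 2 and 3 were 0.16, -0.17 and 0.18, and the list passed without exosome replicate 2 (median 0.14, adjusted p = 0.000712) or replicate 2 of both groups (0.13, 0.000359). The median was -0.06 for p53 targets (0.218; TP53I3, MDM2 and BAX at -0.33, 0.18 and -0.11). The identifier of BAX is listed under DHDH in the reference table, so its value is uncertain. Steroid hormone genes had a median of -0.04 (0.953; ESR1, PGRMC2 and HSD17B4 at -0.20, 0.10 and 0.10). Medians in this paragraph depended on single libraries. Without exosome replicate 2 they were 0.02 for NF-kB signalling, -0.05 for complement, 0.01 for interferon-stimulated genes and 0.01 for steroid hormone genes, and IRF9, CLU, TXNRD1 and PRDX1 passed over all genes tested. Without control replicate 3 they were 0.03 for NF-kB signalling, -0.02 for antigen processing and -0.01 for NRF2 targets.

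Transcripts of sperm and male accessory glands, tested because the vesicles came from semen, did not pass as a list (median log2 change 0.04 over 3 of 32 listed genes, adjusted p = 0.493). ODF2, a sperm tail protein, was at 40.4 ± 1.30 FPKM in the control and 41.5 ± 2.02 in the exosome libraries, MSMB at 24.3 ± 3.81 and 22.5 ± 1.40, and ACPP at 2.22 ± 0.413 and 2.81 ± 0.105. Smooth muscle and pericyte markers had a median of -0.0005 over 3 members (adjusted p = 0.953), with TAGLN, MCAM and NOTCH3 at log2 changes of -0.40, 0.16 and -0.0005. TAGLN passed over all genes tested without exosome replicate 2. Among the stromal markers, VIM was at 556.7 ± 52.4 and 505.3 ± 63.6 FPKM and COL1A2 at 50.9 ± 4.67 and 47.5 ± 2.46. Less abundant members, chosen after their values were seen, were uneven within each group. COL1A1 was at 2.48, 30.0 and 14.7 FPKM in control replicates 1, 2 and 3 and at 20.4, 6.27 and 0.887 in the exosome replicates. COL3A1 was at 0.239, 1.93 and 1.37 and at 2.05, 0.988 and 0.114. The cause was not tested. The stromal list passed without control replicate 1 (median -0.36, adjusted p = 0.0148) or replicate 1 of both groups (-0.30, 0.00132). Its median was 0.03 without exosome replicate 3 and -0.02 without control replicate 2, so its sign rested on single libraries. Lists with fewer than 3 members in the table were not tested. Ciliated epithelium held TUBB4B (330.9 ± 21.6 and 339.7 ± 29.3 FPKM), and endothelium KDR (1.58 ± 0.354 and 1.07 ± 0.0983). Leukocytes were represented by CD68 (6.50 ± 0.955 and 5.88 ± 1.03) and LAPTM5 (4.58 ± 0.238 and 3.62 ± 0.492), and red blood cells HBA (1.55 ± 0.565 and 0.992 ± 0.579).

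Of the 26 lists tested, 8 passed, 3 higher and 5 lower, and with quantile normalization 4 were higher and 4 lower. With an estimated correlation 0 passed in camera (1 at an unadjusted p under 0.05), and 0 in fry's directional test (4 at an unadjusted p under 0.05). Without replicate 3 of both groups 4 lists passed, and 7 of 25 with members of another reference symbol left out.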

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

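The replicate block combined with an estimated correlation, and leaving out list members whose identifier has another symbol in the reference table, were chosen after seeing the data, and the other alternatives were planned. With limma 0 genes passed under every other pseudocount, filter, scaling and variance model, with a 1.5-fold minimum, and with the replicate block, and from 1307 to 1377 genes had an unadjusted p under 0.05 there. At an adjusted p under 0.10 there were 3 genes, by construction of the wider threshold. Leaving out libraries gave from 0 to 297 genes, with 297 without exosome replicate 2, 58 without replicate 2 of both groups, and 1 each without control replicate 3 and without replicate 3 of both groups; the cause was not tested. The smallest adjusted p over these alternatives lay between 0.00386 and 0.340.

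Camera called 8 lists with the other pseudocounts, filters and scalings and with robust variances, 6 without the intensity trend, and 7 of 25 without members of another reference symbol, which lost proinflammatory cytokines (adjusted p = 0.0604). Leaving out libraries gave from 4 lists, without replicate 3 of both groups, to 10, without exosome replicate 2 and also without replicate 1 of both groups. With an estimated correlation 0 lists passed, in fry's directional test 0, and with the replicate block and an estimated correlation 0, with 1, 4 and 0 lists at an unadjusted p under 0.05. In fry's mixed test, which asks for change in either direction, 1 list passed, hypoxia and glycolysis (adjusted p = 0.0170). The first loss came with the correlation measured in these data, which was 0.943 for the cholesterol list and at least 0.0943 for each of the 8 passing lists. The preset of 0.01 lies below these estimates, so the p-values from the preset are too small where the estimates hold. For fry, which does not compare a list with other genes, the cause was not tested. The cholesterol, mitochondrial, cell cycle and endometrial epithelium lists kept their call in 19 of 22 alternatives, all of which used the preset correlation. The 3 alternatives without the preset lost all 8 calls. Epithelial junctions kept it in 17, proinflammatory cytokines in 14, and hypoxia and immediate early genes in 12 each. Over all 8 lists, 131 of 176 values stayed on their side of the threshold, 45 no longer passed and 0 reversed. For 33 genes, the 12 of smallest p and the first 3 members of each passing list, 558 of 594 values stayed, 36 newly passed and 0 reversed, and 25 genes passed without exosome replicate 2. Of the other 62 named by the rule, 12 passed without exosome replicate 2, and PTGS2 and TXNRD1 also without replicate 2 of both groups.

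Whether the replicate numbers pair the samples is not settled. Of the pairs with the same number, 2 of 3 had a correlation of deviations over 0.1, and 3 of 6 libraries correlated best with their own number. The pair numbered 3 was at -0.07. Pairs with different numbers also lay over 0.1, exosome replicate 2 with control replicate 3 (0.169) and exosome replicate 3 with control replicate 1 (0.139). No label says what a number shares. With the replicate block 7 lists passed, 2 higher and 5 lower, with hypoxia and glycolysis at an adjusted p of 0.0674. No DESeq2 or edgeR alternative was run, because the values are not counts. The unknown depth leaves the counting error of low genes open.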

Other observations

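The tests of a swap of libraries and of a lower epithelial share were chosen after the result was seen, and so were the genes described first. The bound for the epithelial share was also made stricter after its value was seen.

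Genes outside the fixed lists included fatty acid desaturases. FADS2 was at 29.6 ± 5.34 FPKM in the control and 13.0 ± 10.2 in the exosome libraries, with exosome replicate 2 at 24.6, FADS1 at 19.3 ± 1.10 and 11.9 ± 5.74, and SCD, the stearoyl-CoA desaturase, at 197.3 ± 39.5 and 129.5 ± 52.2, and the groups overlapped in all 3. AACS, which activates acetoacetate for lipid synthesis, was at 30.2 and 20.8 FPKM, and the secreted phospholipase PLA2G3 at 19.3 and 11.8, with no overlap in either. The keratins KRT14 and KRT9 were at 51.8 and 35.0 FPKM and at 66.5 and 49.1, and SPRP at 12.9 and 5.88. None of these passed over all genes tested with all libraries in, and FADS2, FADS1, SCD, AACS, PLA2G3 and SPRP passed without exosome replicate 2.

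A hypothesis was that fatty acid synthesis genes, which share regulators with cholesterol synthesis, move with the cholesterol genes. Over 11 such genes the median log2 change was -0.167, with 9 lower and 2 higher, between the bounds set for either outcome, so the hypothesis stays open. A hypothesis that other aryl hydrocarbon receptor targets move with CYP1A1 stays open, since of those listed for the test only TIPARP was in the table. The log2 change of TIPARP, -0.2659, lay past the bound set in advance for the hypothesis, with no overlap between groups. TIPARP is 1 gene and did not pass over all genes tested in limma (adjusted p = 0.284). NQO1, a target not on that list, was at 0.44 and did not pass. Its groups overlapped, with exosome replicate 2 at 57.4 FPKM, below the controls (70.9 to 91.5), and replicates 1 and 3 at 141.7 and 171.7, and it passed without replicate 2.

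After median rescaling or quantile normalization, the median nearer 0 was -0.4957 for the cholesterol list and -0.2368 for the mitochondrial list. Median rescaling could hardly move a list, since the median log2 change of all genes was already -0.00229, so it was no test of scaling. Both falls remained under quantile normalization. The library medians already lay close together, from 14.71 to 14.95 FPKM. Quantile normalization could thus hardly move the cholesterol list either, and it was no test of scaling for that list. The mitochondrial median moved from -0.34 under quantile normalization, so part of that fall depended on the scaling and the rest remained. Of the 10 splits of the 6 libraries into 3 and 3, 2 gave as many passing lists, with 8 for the real split and 11 for the highest other, and 10 gave as many genes, with 0 for both. These splits are too few for a share under 0.05. The split with 11 lists set exosome replicates 1 and 3 and control replicate 1 against the rest, with 1563 genes at an unadjusted p under 0.05 against 1362. A response to the exosomes stays open as a hypothesis.

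Exosome replicate 2 lay near the controls on the cholesterol list. Over 200 genes chosen without it, its median position between the control mean (0) and the mean of the other exosome libraries (1) was 0.1878. Left-out control replicates 1, 2 and 3 lay at 0.2352, -0.0464 and -0.0073, each over genes chosen with fewer control libraries. Exosome replicate 2 lay above control replicates 2 and 3. Only through control replicate 1 was it inside the range of the controls, as a mislabelled control library would be. Other values count against that: mitochondrial transcripts made up 5.81% of its FPKM against 6.25% to 6.42% in the controls, and its list medians lay beyond every control for the mitochondrial (-0.16 against -0.04 to 0.02) and endometrial epithelium lists (-0.09 against -0.03 to 0.02), and CYP1A1 (5.59 FPKM against 35.4 to 80.9), ANKH (80.9 against 157.5 to 209.1), ENC1 (172.8 against 120.5 to 133.1) and CRYM (31.8 against 43.4 to 46.4) did so too. Both lists and all of these genes also passed without this library. The naming rule, however, required this library to lie beyond the controls in these genes. They were thus picked with its values, and mislabelling stays open. A swap with control replicate 1 is argued against, since that library lay below the left-out exosome library by 0.574 and 0.6706 in position. Other values go the other way. Control replicate 1 lay at 0.17 and 0.25, and exosome replicate 2 at much the same positions, 0.27 and 0.18. The split that amounts to this swap gave 11 passing lists against 8 for the real one, so a swap is not excluded. A weaker response of that culture or exosome preparation also stays open and was not tested.

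Lower epithelial markers may come from a lower share of epithelial cells, which would raise the markers of other cell types. The 10 stromal and smooth muscle markers had a median log2 change of -0.1062, 8 of them lower. A 95% bootstrap interval ran from -0.3327 to 0.0621. It was made by resampling the genes as if independent, so it does not measure the spread between libraries. The bound first set against a lower share, an interval below 0.1 over all 10 markers, was met. Since that interval leaves out the spread between libraries, meeting it does not decide the question. The stricter bound asked the same of markers at moderate levels. The abundant CD90 and VIM have a high baseline that would hide a small share. The 4 markers with a mean of 5 to 100 FPKM had an interval from -0.8417 to 0.1612. With so few genes these bounds are the lowest and highest of the 4 values, those of COL1A1 and MCAM. MCAM alone thus put the interval past 0.1. COL1A1, 1 of these 4, lay between 0.887 and 20.4 FPKM within the exosome group. The stricter bound therefore could not decide, and a lower epithelial share and lower expression per cell cannot be told apart here.

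The deposited table opened with 184 genes sorted apart from the 10731 that followed. Of these 184, 114 were lower and 70 higher in the exosome libraries, the smallest log2 ratio of means was 0.32 in size, 164 were at an unadjusted p under 0.05 in limma, and 19 of the 22 cholesterol genes tested were among them. Nothing in the table says how they were chosen.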
